A study of Rattus norvegicus with 26 samples.

How the data were processed

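Hippocampal RNA of male F344 rats aged 18 months was measured on the Rat Gene 1.0 ST platform of Affymetrix, with 1 array for each of 26 rats. The rats had eaten a purified diet with 100 (low), 1000 (control) or 10000 IU (high) of vitamin D3 per kg, and 8, 9 and 9 arrays came from these diets. Per the labels' protocols the RNA was extracted with TRIzol. The rats were housed in pairs, and a mark on the tail told cage mates apart. Cage numbers were read from the array descriptions, which gave 14 cages, 12 of them with both rats measured. The descriptions carry 1 common batch tag, so the labels name no separate batches. RNA quality values, serum vitamin D and behaviour were not analysed here.

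The deposited table holds log2 probe set values made by the authors. Per the submitters' processing notes, Partek 6.6 and GCRMA were used, with no role given for either. The table has 29214 probe sets and 0 missing values, with values between 4.28 and 15.4, and no pair of arrays was identical. The medians of the arrays lay between 6.92 and 6.96, so no further normalization was applied in the fit that is reported. The number of arrays limits the precision of the values.

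In the array annotation, 15310 probe sets had 1 gene symbol, 323 had several and 13581 had none. Of the gene IDs of the first group, 15279 were found in the RefSeq gene table of assembly GRCr8, and 0 symbols needed an update. For each of 14506 genes the probe set with the highest mean over all arrays was kept, and a gene was tested if that mean was at or above 6.94, the median of all probe sets, which left 8485 genes.

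Linear models were fitted with limma 3.58.1 in R 4.3.3, with the 3 diets as a factor over all 26 arrays. A moderated F-test compared the diets, and moderated contrasts gave high minus low, high minus control and low minus control. Marked and unmarked rats were compared with diet in the model, as a comparison in which no difference by diet enters. All tests were 2-sided, and p values were adjusted by the Benjamini-Hochberg method over all tested genes. A gene was called at an adjusted p under 0.17, the stricter of the false discovery rates named in the series design, and counts at 0.05 and 0.31 were computed too. Genes in the F-test were also assigned to the template with the highest absolute Pearson correlation: low apart, control apart, high apart or graded.

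Before the data were examined, 27 gene lists with 620 distinct gene symbols were fixed, covering pathways, cell types of the tissue and neighbouring regions. The 23 lists with at least 5 tested genes were compared with limma's camera at its preset correlation of 0.01, adjusted over 69 tests, and called at an adjusted p under 0.05. The tests were repeated with a correlation estimated for each list. At the preset correlation most splits of the rats that ignored diet also called lists, as the closing part gives. Adjusted p values at the preset correlation alone therefore do not show a difference by diet. The mean value of a list's tested genes in each rat served as its score. Scores were also compared by exact permutation of the rats, with 24310 regroupings for 8 against 9 rats and 48620 for 9 against 9. These regroupings took cage mates as independent, so the exact permutation p values of the list scores do not account for cages. The thresholds, the contrasts, the rule for the genes named and all alternatives were likewise fixed before the data were examined, except where the closing part says otherwise.

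The genes named were, for each contrast, called genes filled up to 5 per direction with those of the smallest unadjusted p, and the 10 genes of smallest p in the F-test. Of each called list the 4 members with the smallest p were named, and 2 genes for the tail mark. Vdr, Cyp24a1, Cyp27b1, Rxra and Cyp27a1 were always named.

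The alternatives were no intensity filter, a stricter intensity filter at 9.20, every probe set on its own, quantile normalization, centring on array medians, cage as a random block, array quality weights, an intensity trend with a robust prior, only the diets compared, the tail mark as a covariate, removal of values over 2 SD from their diet mean, tests without moderation, other thresholds, a linear trend over log10 dose and each array left out in turn. The fit was also repeated without the 3 arrays of lowest quality weight. The consensus correlation of cage mates was 0.136. Correlations between list scores were computed over rats and, as an alternative chosen after seeing the data, over the means of 14 cages.

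The procedure was tested on simulated data built on the measured spread. On the high diet 200 genes were shifted together, 67 by 0.25, 67 by 0.5 and 66 by 1 log2, with independent noise for each gene. Of the 67 genes shifted by 0.25 log2, 65 were called between high and low and 66 between high and control. All genes with larger shifts were called. So many large shifts ease the adjusted threshold, so the run does not give the power for few genes shifted by 0.25 log2. Between high and low 35 unshifted genes were called as well, and 27 between high and control.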

Results

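Gene expression in the hippocampus was compared among aging male rats that had eaten a diet low in vitamin D3, a control diet or a diet high in vitamin D3, to see whether the amount of the vitamin alters it. There were 8 rats on the low, 9 on the control and 9 on the high diet. Values are log2 intensities of 8485 genes. The mean correlation of an array with the others lay between 0.993 and 0.997, and the number of arrays limits the precision, with a median SE of 0.036 log2 for the difference between high and low.

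Across the 3 diets, the genes that stood out most were Polr1b, a subunit of RNA polymerase I, and Slc17a6, the vesicular glutamate transporter VGLUT2. Polr1b (probe set 10839751) had means of 8.47 ± 0.06 on low, 8.51 ± 0.05 on control and 8.61 ± 0.07 on high (SD, n = 8, 9 and 9). Slc17a6 (probe set 10707325) had means of 7.15 ± 0.20, 7.32 ± 0.22 and 7.66 ± 0.30 in the same order. Rad17, a DNA damage checkpoint gene, and Pnoc, the precursor of nociceptin, had a control group apart from the others. Commd1, Rbm5, Nmbr, Rbm28, Lxn and Trhr had a high group apart. The moderated F-test of limma called 0 of these or any other genes, with a smallest adjusted p of 0.756. At an unadjusted p under 0.05 there were 392 genes, 4.62% of those tested, and under 0.01 there were 65, or 0.766%. These shares are no larger than chance gives at those levels. The test without moderation also called 0, with 376 genes at an unadjusted p under 0.05. Of the 392 genes, 168 best matched a high group apart, 124 a graded change, 58 a low group apart and 42 a control group apart. With no more genes than chance gives, these pattern counts do not show a response to diet. With values over 2 SD from their diet mean removed, 16 genes were called, while in the unmoderated test this removal raised the mean count at an unadjusted p under 0.05 over other groupings of the same rats from 443 to 762. Without control rat 17 the F-test called 1 gene, Fabp3 (adjusted p = 0.0214), and without high rat 25 it called 3, Slc17a6 (0.018), Lxn (0.0495) and Nmbr (0.0495). Fabp3, a fatty acid binding protein, lies outside the rule for named genes and was chosen after its values were seen.

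Between the high and low diets, the high-diet rats had higher mean levels of Slc17a6, Polr1b, Trhr, Dner and Sucla2 and lower levels of Commd1, Xrcc1, Prom1, Rbm5 and Fn1, but none of these genes passed the adjusted threshold. Slc17a6 had the highest difference of all tested genes, +0.52 log2 (SE 0.11, a ratio of 1.43), and 8 of 9 high-diet rats lay above every low-diet rat. Trhr, the receptor of thyrotropin-releasing hormone, differed by +0.36 (SE 0.09), and Polr1b by +0.14 (SE 0.03) with 9 of 9 high-diet rats above the low mean. Dner, a neuronal transmembrane protein, differed by +0.11 and Sucla2, a subunit of mitochondrial succinate-CoA ligase, by +0.095. Among genes with lower means, fibronectin (Fn1) differed by -0.25, Commd1, which takes part in copper homeostasis, by -0.19, the membrane glycoprotein Prom1 by -0.15, the DNA repair gene Xrcc1 by -0.15 and the splicing regulator Rbm5 by -0.085. Latexin (Lxn), a carboxypeptidase inhibitor, differed by +0.20, and Nmbr, the neuromedin B receptor, by +0.16.

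In limma, 0 genes were called between high and low at an adjusted p under 0.17. The smallest adjusted p was 0.286, for Polr1b and Slc17a6, so that in this fit these 2 genes passed only at the looser threshold of 0.31. At an unadjusted p under 0.05 there were 613 genes, 7.22% of those tested. Of these 382, or 62.3%, were higher on the high diet, against 62.4% with quantile normalization and 53.7% after centring on array medians. The unmoderated test also called 0, with 577 genes at an unadjusted p under 0.05, and a trend over log10 dose called 0, with 644. The 95% interval of the difference lay within 1.2-fold either way for 97.9% of genes. The count was 30 with values over 2 SD removed, 1 (Polr1b) with quantile normalization and 1 (Polr1b) with the tail mark as a covariate. Leaving out 1 rat gave calls in 5 cases: Slc17a6 and Sucla2 without low rat 2 (both adjusted p = 0.152), Polr1b without low rat 3 (0.123), Polr1b and Slc17a6 without control rat 17 (both 0.145), Polr1b without high rat 22 (0.0802), and Slc17a6 (0.00598), Lxn (0.0481) and Nmbr (0.0779) without high rat 25.

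Blood vessel genes fell on the high diet relative to low in the camera test at its preset correlation, a call that was lost with an estimated one. Of the 15 tested markers of endothelial and mural cells, 14 had a lower mean on high, with a median difference of -0.066 log2 and an adjusted camera p of 1.19e-05, but adjusted p = 0.114 with an estimated correlation. Among them, the pericyte gene Rgs5 differed by -0.13, the VEGF receptor Flt1 by -0.10, the junction gene Esam by -0.10 and the smooth muscle actin Acta2 by -0.056. Of these markers 0 passed over all genes and 4 passed when adjusted over the list alone, at the gene threshold of 0.17, or 1 at 0.05. The mean of the list per rat was 8.58 ± 0.04 on low and 8.52 ± 0.04 on high, lower in 9 of 9 high-diet rats than the low mean (exact permutation p = 0.00843, adjusted p = 0.145). The markers of the hippocampal CA1 field also fell in the camera test, with 5 of 6 lower, a median of -0.062 and an adjusted p of 0.0307, but adjusted p = 0.781 with an estimated correlation. Wfs1, an endoplasmic reticulum protein, differed by -0.24, and Zbtb20, a transcription factor, by -0.081, with Fibcd1 at -0.085 and Mpped1 at -0.030. Adjusted over the list alone 2 of the CA1 genes passed at 0.17 and 0 at 0.05, against 0 over all genes, and the mean per rat gave an exact permutation p of 0.0981 (adjusted p = 0.564). The call of the CA1 list was lost without low rat 4 (adjusted p = 0.0594), low rat 7 (0.0645), low rat 8 (0.0626), high rat 19 (0.134, median -0.035) or high rat 25 (0.0539). It was also lost with no intensity filter (0.061), with array quality weights (0.152, median -0.035) and without the 3 arrays of lowest weight (0.123, median -0.027). Calcium channel and calcium handling genes fell in the camera test, with 27 of 38 lower, a median of -0.022, a mean of -0.0026 and an adjusted p of 0.0162, but adjusted p = 0.781 with an estimated correlation. The mean of the calcium list per rat differed by -0.0026 (SE 0.011, exact permutation p = 0.809, adjusted p = 0.987). The ryanodine receptor Ryr3 differed by -0.12, the inositol trisphosphate receptors Itpr1 and Itpr2 by -0.078 and -0.065, and the T-type channel Cacna1g by +0.18. Of the calcium genes 0 passed over all genes and 0 when adjusted over the list alone, and the call was lost without low rat 4 (0.0594, median -0.013) or high rat 19 (0.121, median -0.00996), as well as with no intensity filter (0.101) and with values over 2 SD removed (0.102, median -0.014). Markers of neighbouring cerebral cortex had higher means on high in the same comparison, as given with the lists that rose.

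In the camera test at its preset correlation, the lists of neighbouring cortex, cholesterol synthesis, oxidative phosphorylation, GABA signalling and the presynaptic vesicle cycle each rose on the high diet relative to low. None of these 5 calls held with an estimated correlation (adjusted p = 0.172, 0.530, 0.631, 0.575 and 0.781 in that order), and whether the lists moved jointly was not tested. At the preset correlation 90 of 99 other splits of the rats of these diets also called at least 1 list, with a mean of 3.08 lists. All 6 tested cortical markers had higher means, with a median of +0.096 log2 and an adjusted camera p of 3.96e-04, but adjusted p = 0.172 with an estimated correlation. The cortical transcription factor genes Fezf2, Nr4a2 and Etv1 differed by +0.18, +0.11 and +0.096, and the pseudokinase gene Trib2 by +0.095. Of the cortical genes 0 passed over all genes and 5 when adjusted over the list alone at 0.17, or 3 at 0.05. The mean of the cortical list per rat was 10.00 ± 0.04 on low and 10.11 ± 0.07 on high (exact permutation p = 0.00485, adjusted p = 0.112). After removal of the diet means, this score and Slc17a6 varied together over 26 rats (Pearson r = 0.778, permutation p = 1e-05, the smallest that 100000 permutations can give; Spearman rho = 0.695, permutation p = 0.00018; r = 0.673 without the 2 rats farthest from the median; adjusted p = 3e-05 over 3 relations). These permutations took cage mates as independent, and over the means of 14 cages r was 0.835 (permutation p = 0.00561, adjusted p = 0.0168; rho = 0.697, permutation p = 0.0359; r = 0.608 without the 2 farthest cages). In cholesterol synthesis, 15 of 17 genes were higher, with a median of +0.058 and an adjusted p of 3.96e-04, but adjusted p = 0.530 with an estimated correlation. Dhcr7 and Sc5d, enzymes of the last steps, differed by +0.16 and +0.061, and Fdps and Nsdhl by +0.10 and +0.071, with 0 genes passing over all genes and, adjusted over the list alone, 11 at 0.17 and 0 at 0.05 (smallest such adjusted p 0.128). The mean of this list per rat gave an exact permutation p of 0.0328 (adjusted p = 0.247). In oxidative phosphorylation, 44 of 50 genes were higher, with a median of +0.028 and an adjusted p of 3.96e-04, but adjusted p = 0.631 with an estimated correlation. The ATP synthase gene Atp5f1a differed by +0.070, the cytochrome oxidase gene Cox4i1 by +0.069 and the complex I genes Ndufs1 and Ndufa1 by +0.060 and +0.11, and the mean per rat gave an exact permutation p of 0.0239 (adjusted p = 0.206).

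In GABA signalling, 19 of 22 genes were higher on high than on low, with a median of +0.037 and an adjusted p of 0.00807, but adjusted p = 0.575 with an estimated correlation. Gad1, which makes GABA, differed by +0.074, the vesicular transporter Slc32a1 by +0.087, and the receptor subunits Gabra3 and Gabrg3 by +0.15 and +0.18. The mean of the GABA list per rat was 10.95 ± 0.02 on low and 11.00 ± 0.02 on high (exact permutation p = 0.00169, adjusted p = 0.0582), and without high rat 23 its median was +0.025, with the call kept (adjusted p = 0.00905). In the presynaptic vesicle cycle, 29 of 37 genes were higher, with a median of +0.024 and an adjusted p of 0.0127, but adjusted p = 0.781 with an estimated correlation, 0.0724 with quantile normalization and 0.0544 without high rat 21. Synj1, Sv2a, Syn2 and Ap2a1, which act in vesicle release and recycling, differed by +0.042, +0.057, +0.046 and +0.042, and the mean per rat gave an exact permutation p of 0.0357 (adjusted p = 0.247). Of the genes of GABA signalling, the vesicle cycle and oxidative phosphorylation, 0 passed over all genes and 0 when adjusted over the list alone. Camera called 8 lists between high and low, 0 of them with an estimated correlation and 0 by exact permutation, and 15 lists were not called. A stricter intensity filter left 3 calls of the 5 lists that could still be tested, with GABA signalling (adjusted p = 0.052) and the vesicle cycle (0.0572) lost, while the vessel, cortical and CA1 lists had 4 genes each over that filter, too few to test. In all 16 list calls of the 3 contrasts the median, the mean and the test had the same sign, and among the 53 tests without a call these differed in sign in 12.

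**Figure D1:**
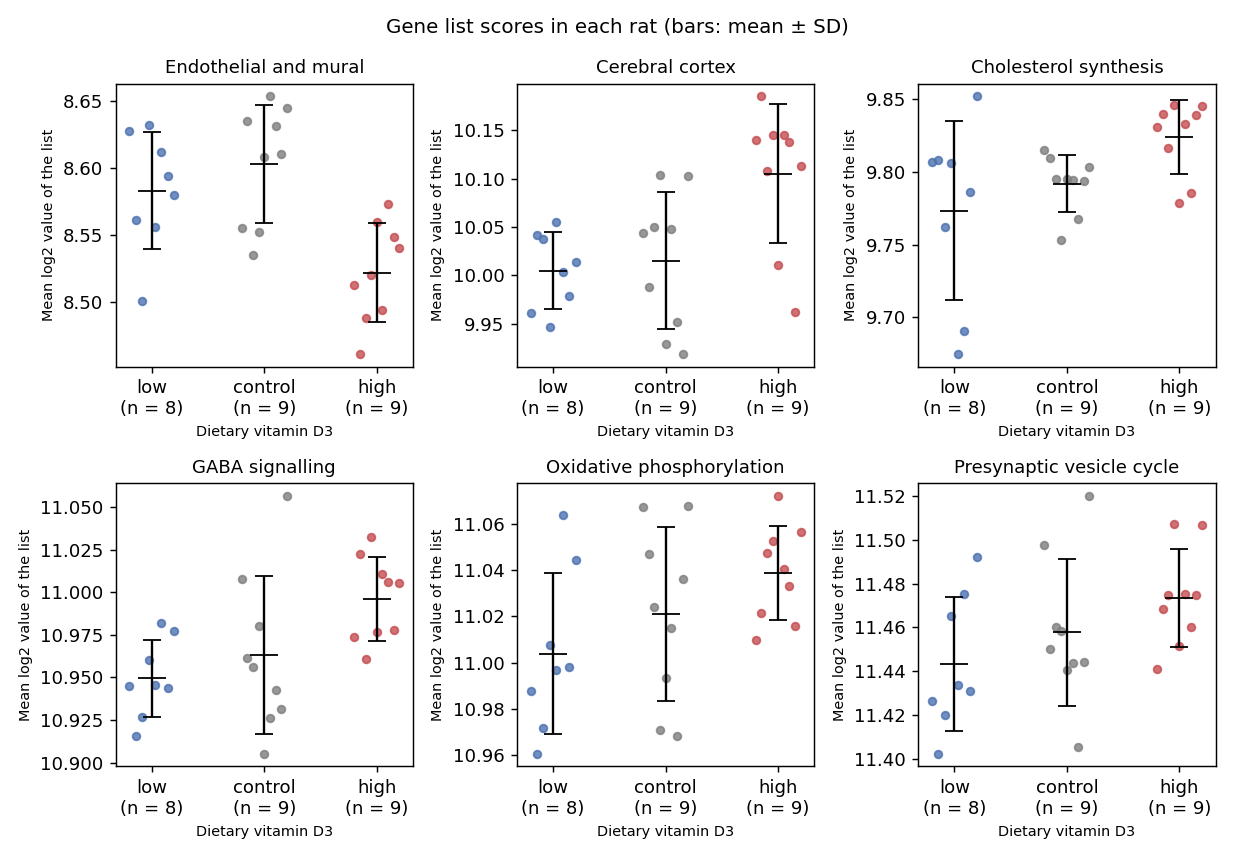
Mean log2 value of the tested genes of 6 lists in each rat, by diet; each point is a rat, and the bars show the mean ± SD. The endothelial and mural mean on the high diet, 8.52, lies below those on low, 8.58, and control, 8.60, while the cortical mean on high, 10.11, lies above both others, 10.00 and 10.02.

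Between the high and control diets, the high-diet rats had higher mean levels of Pnoc, Nmbr, Trib2, Polr1f and Uhmk1 and lower levels of Rbm28, Commd1, C8g, Tia1 and Rbm5, none of which passed the adjusted threshold. Pnoc was 6.98 ± 0.10 on control and 7.19 ± 0.14 on high, a difference of +0.21 log2 (SE 0.05). Nmbr differed by +0.17, Trib2 by +0.16, Polr1f, a further subunit of RNA polymerase I, by +0.14, and the kinase gene Uhmk1 by +0.085, though its other probe set had the opposite sign. The nucleolar gene Rbm28 differed by -0.17, Commd1 by -0.17, the complement gene C8g by -0.16, the RNA-binding protein gene Tia1 by -0.096 and Rbm5 by -0.086. In limma 0 genes were called, with 393 at an unadjusted p under 0.05, a smallest adjusted p of 0.921 and 430 genes at that unadjusted level in the unmoderated test, which also called 0. Of the 393 genes 185, or 47.1%, were higher on high, against 57.0% with quantile normalization and 50% after centring, so the majority direction depended on the scaling. The interval of the difference lay within 1.2-fold for 98.5% of genes. With values over 2 SD removed 15 genes were called. Without control rat 17 Fabp3, chosen after its values were seen, was called (adjusted p = 0.00653), and without high rat 25 Nmbr was called (0.125).

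Blood vessel genes fell on the high diet relative to control as well, and this call held with an estimated correlation. The test with an estimated correlation took cage mates as independent, and no fit combined it with cage as a block. All 15 tested markers of endothelial and mural cells had lower means on high, with a median of -0.079 log2 and an adjusted camera p of 9.95e-10, and adjusted p = 0.0165 with an estimated correlation. Esam differed by -0.13, Rgs5 by -0.12, the drug transporter Abcb1a by -0.12 and the tight junction gene Cldn5 by -0.097. Of these markers 0 passed over all genes and, adjusted over the list alone, 11 at 0.17 and 0 at 0.05 (smallest such adjusted p 0.0524). The mean of the list per rat was 8.60 ± 0.04 on control and 8.52 ± 0.04 on high, and 5 of 9 high-diet rats lay below every control rat (exact permutation p = 0.00132, adjusted p = 0.0582). Cortical markers rose in the same comparison, with 6 of 6 higher, a median of +0.090 and an adjusted p of 1.32e-04, but adjusted p = 0.136 with an estimated correlation. Trib2 differed by +0.16, Nr4a2 by +0.15, Etv1 by +0.096 and Fezf2 by +0.084, with 0 passing over all genes and 3 when adjusted over the list alone, at 0.17 and at 0.05 alike, and the mean per rat gave an exact permutation p of 0.0182 (adjusted p = 0.192).

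Further lists rose on high relative to control in the camera test, and none of these calls held with an estimated correlation. In cholesterol synthesis 15 of 17 genes were higher, with a median of +0.030 and an adjusted p of 0.00775, but adjusted p = 0.703 with an estimated correlation, and Idi1, Insig1, Sc5d and Nsdhl differed by +0.11, +0.083, +0.051 and +0.051. In GABA signalling 19 of 22 were higher, with a median of +0.029 and an adjusted p of 0.0119, but adjusted p = 0.590 with an estimated correlation, and the subunits Gabra2, Gabrg3 and Gabra4 differed by +0.073, +0.15 and -0.066 and Slc32a1 by +0.070. Without control rat 13 the GABA call was lost (adjusted p = 0.0735), and without control rat 17 its median was +0.044. In oxidative phosphorylation 35 of 50 were higher, with a median of +0.016 and an adjusted p of 0.0127, but adjusted p = 0.781 with an estimated correlation, and Ndufa1, Atp5f1a, Atp5mc3 and Ndufs1 differed by +0.15, +0.072, +0.050 and +0.048. That call was lost without control rat 12 (0.0591, median +0.0094), control rat 15 (0.0856) or high rat 22 (0.0721), and the median was +0.00997 without high rat 26. In the presynaptic vesicle cycle 24 of 37 were higher, with a median of +0.017 and an adjusted p of 0.0197, but adjusted p = 0.786 with an estimated correlation, and Ap2a1, Vamp1, Rab3a and Synj1 differed by +0.051, +0.050, +0.046 and +0.028. It was lost without control rat 10 (0.0534), control rat 15 (0.121, median +0.0092), control rat 16 (0.0615), high rat 21 (0.0913) or high rat 26 (0.0533). Of the genes of these lists 0 passed over all genes and 0 when adjusted over the list alone. The means per rat of the cholesterol, GABA, oxidative phosphorylation and vesicle lists gave an exact permutation p of 0.0108, 0.0777, 0.230 and 0.262 (adjusted p = 0.149, 0.488, 0.903 and 0.903). The cortical mean per rat lay above the control mean in 7 of 9 high-diet rats, and the vessel mean lay below it in 9 of 9. Over the means of 14 cages the relation of these scores did not pass 0.05 (r = -0.395, permutation p = 0.262, adjusted p = 0.393). Both contrasts with the high diet share the same high-diet rats. A stricter intensity filter left 0 of the 4 called lists that could still be tested, these being the lists of this paragraph, while the vessel and cortical lists had 4 genes each over that filter, too few to test. Quantile normalization and no filter each left 3 of the 6 calls, those of the vessel, cortical and cholesterol lists, and the cholesterol call was lost without the 3 arrays of lowest weight (0.0571).

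Between the low and control diets, the low-diet rats had higher mean levels of Adcy8, Pnoc, Cyp20a1, Cdh10 and Zfp13 and lower levels of Cavin3, Rad17, Topors, St3gal6 and Wdfy1, none of which passed the adjusted threshold. Rad17 was 7.71 ± 0.07 on control and 7.57 ± 0.07 on low, a difference of -0.14 log2 (SE 0.03), and was lower than the control mean in 8 of 8 low-diet rats. The calcium-stimulated adenylyl cyclase Adcy8 differed by +0.20, Pnoc by +0.16, Cyp20a1 by +0.10, the cadherin gene Cdh10 by +0.089 and Zfp13 by +0.076. The caveolar gene Cavin3 differed by -0.16, Topors by -0.14, the sialyltransferase gene St3gal6 by -0.10 and Wdfy1 by -0.083. In limma 0 genes were called, with 193 at an unadjusted p under 0.05, 2.27% of those tested, a smallest adjusted p of 0.819 and 167 genes at that unadjusted level in the unmoderated test, which also called 0. Of the 193 genes 56, or 29.0%, were higher on low, against 41.9% with quantile normalization and 42.1% after centring. The interval of the difference lay within 1.2-fold for 98.7% of genes.

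Microglial and CA1 markers rose on low relative to control in the camera test, and neither call held with an estimated correlation. Of the 18 microglia and complement genes 15 were higher on low, with a median of +0.041 and an adjusted p of 0.00333, but adjusted p = 0.781 with an estimated correlation. The complement gene C1qc differed by +0.14, the receptor Gpr34 by +0.073, cathepsin S (Ctss) by +0.060 and the CSF1 receptor Csf1r by +0.046, and the list's mean was above the control mean in 4 of 8 low-diet rats. Without low rat 5 the sign of the microglial list turned, to a median of -0.0061 (adjusted p = 0.925). The microglial call was also lost with no intensity filter (0.061), with values over 2 SD removed (0.819, median +0.0084) and without the 3 arrays of lowest weight (0.0608). All 6 CA1 markers were higher on low, with a median of +0.053 and an adjusted p of 0.0197, but adjusted p = 0.781 with an estimated correlation. Wfs1, Man1a1, Fibcd1 and Zbtb20 differed by +0.11, +0.083, +0.074 and +0.033. The CA1 call was lost without low rat 4 (0.0758), low rat 7 (0.0626), control rat 10 (0.0591), control rat 15 (0.0504) or control rat 17 (0.286, median +0.021). It was also lost with no intensity filter (0.196, median +0.033), with array quality weights (0.241, median +0.018), with values over 2 SD removed (0.141, median +0.028) and without the 3 arrays of lowest weight (0.312, median +0.0096). In these lists 0 genes passed over all genes and 0 when adjusted over the list alone, and the means per rat gave an exact permutation p of 0.583 for microglia (adjusted p = 0.987) and 0.211 for CA1 (0.903). The count of 2 called lists became 4 without low rat 1, 1 without low rat 5, 6 without low rat 6 and 1 without control rat 10. The 3 lists called with no filter were others, namely choroid plexus, oxidative phosphorylation and thalamus, all lower on low (adjusted p = 0.00432, 0.0424 and 0.0186), and the list called with removal (0.0271) and without the 3 arrays (0.00534) was that of immediate early genes, higher on low. This list was also called with array quality weights (0.00616) and without low rat 1 (0.0475), low rat 2 (0.0416) or control rat 17 (0.0166), and, higher on high than on control, with weights (0.0309) and without the 3 arrays (0.0405). All these calls used the preset correlation. Over all rats an estimated correlation gave the immediate early genes an adjusted camera p of 0.786 in both contrasts with control.

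The vitamin D receptor and the enzyme genes Cyp24a1, Cyp27b1 and Cyp27a1 had levels below the filter on all diets, while Cyp2r1, also of vitamin D metabolism, was over it. Vdr was 5.30 ± 0.09 on low, 5.28 ± 0.05 on control and 5.26 ± 0.05 on high. Cyp24a1, the catabolic enzyme that the receptor induces in many tissues, was 5.39 ± 0.09, 5.40 ± 0.08 and 5.36 ± 0.05, and Cyp27b1, which makes the active hormone, was 5.89 ± 0.04, 5.88 ± 0.04 and 5.88 ± 0.02. Cyp27a1 was 6.52 ± 0.07, 6.61 ± 0.11 and 6.59 ± 0.10. The partner receptor Rxra was over the filter at 8.45 ± 0.12, 8.43 ± 0.13 and 8.50 ± 0.08, with a limma adjusted p of 0.858 between high and low. The list of receptor and metabolism genes had 5 tested members, with a median of +0.0063 between high and low and an adjusted p of 0.512, and 1 member, Dhcr7, passed when adjusted over the list alone, at 0.17 and at 0.05, against 0 over all genes. Dhcr7 also belongs to the cholesterol list. Of the 19 textbook target genes of the receptor on the array only 6 were tested, and the others, Cyp24a1 among them, lay below the filter. Of the 6, 5 also belong to other lists. Between high and low 5 of the 6 were lower on high, with a median of -0.065 and an adjusted camera p of 0.273. So few members say little about the receptor's targets.

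**Figure D2:**
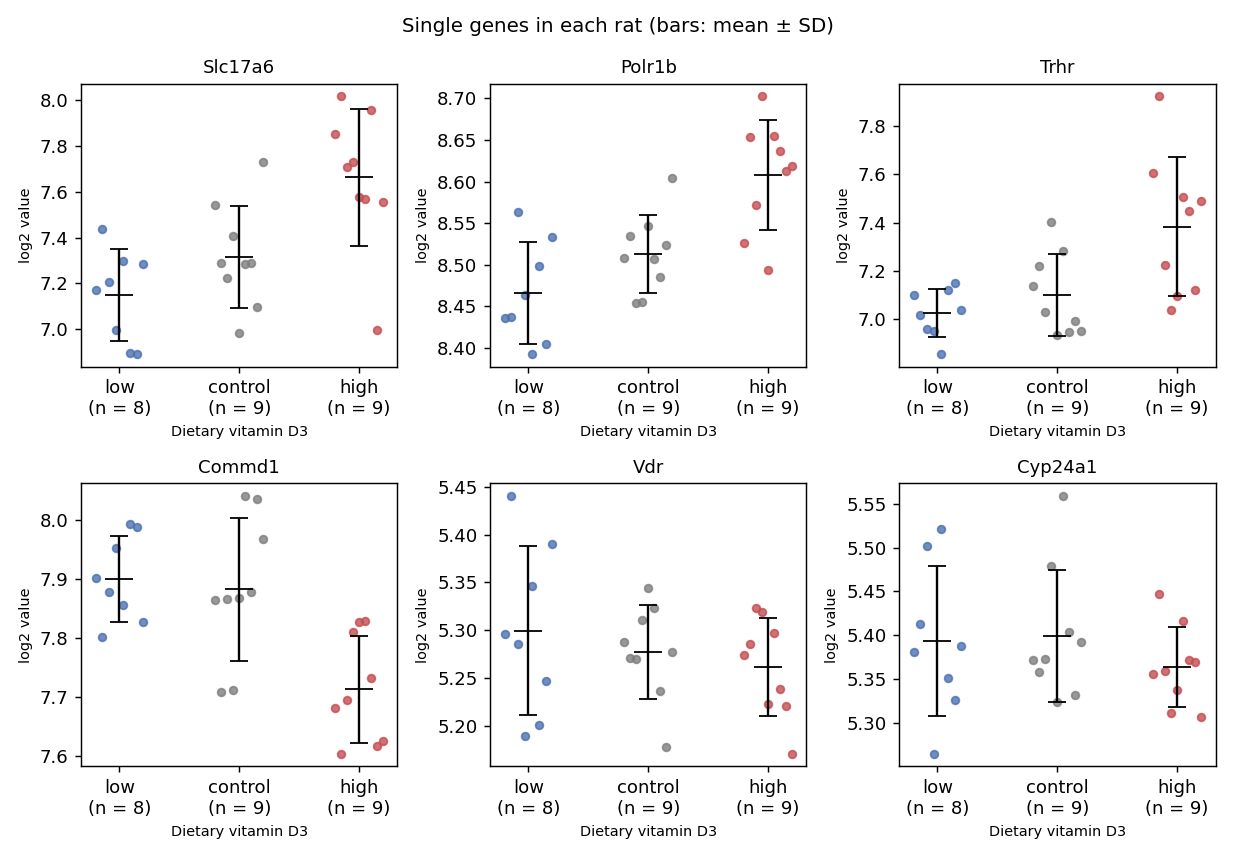
Log2 values of Slc17a6, Polr1b, Trhr, Commd1, Vdr and Cyp24a1 in each rat, by diet; each point is a rat, and the bars show the mean ± SD. Slc17a6 has means of 7.15, 7.32 and 7.66 on low, control and high with 1 high-diet rat at 7.00, and the Vdr means lie between 5.26 and 5.30.

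Marked and unmarked rats were compared as a contrast that carries no diet, with diet but not cage in the model. The smallest p values were those of Txndc15, at -0.096 log2 in marked rats (SE 0.02), and the deacetylase gene Hdac6, at -0.084 (SE 0.02). Neither passed, with a limma adjusted p of 0.892 for both. In limma 0 genes were called, with 451 at an unadjusted p under 0.05, and the unmoderated test called 0, with 441. With cage as a random block 606 genes were at an unadjusted p under 0.05 and 0 were called. Of the 451 genes 66, or 14.6%, were higher in marked rats, against 41.1% with quantile normalization and 47.0% after centring. Without high rat 21 Txndc15 was called (adjusted p = 0.103).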

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

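The tests of thalamic markers, of means per cage, of the endothelial against the mural genes and of the exact permutation p for the cortical and vessel lists were chosen only after the results they concern were seen.

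A single rat stood far from the others of its diet in 23 of 234 gene and diet groups (9.83%) and in 7 of 69 list score and diet groups (10.1%), where chance gives about 5%. Of these 30, control rat 17 accounts for 6, high rat 19 for 5 and low rat 5 for 5. In low rat 5, Ctss was 12.54 (next 12.27), Csf1r 10.57 (next 10.35) and C1qc 10.03 (next 9.07). The microglial list score of that rat was 10.02 (next 9.69) and its score for antigen presentation and interferon response was 9.95 (next 9.19). In high rat 19, the CA1 list score was 10.21 (next 10.49), Wfs1 was 10.99 (next 11.89), Zbtb20 11.73 (next 11.88), Fibcd1 9.74 (next 9.99) and Itpr1 11.20 (next 11.38). In control rat 17, Gabra3 was 11.82 (next 11.42), Cacna1g 9.35 (next 8.95), Ryr3 9.71 (next 9.94) and Zbtb20 11.71 (next 11.95). The score of activity-induced immediate early genes in that rat was 9.95 (next 9.73) and its CA3 score 10.20 (next 10.30). In high rat 25, Slc17a6 was 7.00 (next 7.56) and C8g 8.81 (next 8.99). In low rat 4, Xrcc1 was 8.73 (next 8.52), Zbtb20 12.07 (next 12.02) and the circadian clock score 10.14 (next 10.03). In low rat 8, Uhmk1 was 11.01 (next 10.96), Fdps 11.10 (next 10.91) and Sv2a 11.66 (next 11.59). In control rat 12, Synj1 was 12.26 (next 12.20), Ctss 12.08 (next 12.17) and the ribosomal protein score 10.44 (next 10.50). Gabra3 was 11.70 in low rat 7 (next 11.38), Adcy8 9.01 in high rat 23 (next 8.77) and Rad17 7.50 in high rat 20 (next 7.60).

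The cortical list and Slc17a6 were both higher on the high diet, and after removal of the diet means they varied together over 26 rats (Pearson r = 0.778, permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 3e-05 over 3 relations; Spearman rho = 0.695, permutation p = 0.00018). Without the 2 rats farthest from the median (high rat 25 and control rat 16) r was 0.673, and within low, control and high it was 0.651, 0.777 and 0.843, while over the means of 14 cages it was 0.835 (permutation p = 0.00561, adjusted p = 0.0168; rho = 0.697, permutation p = 0.0359; r = 0.608 without the 2 farthest cages). This is consistent with an uneven share of neighbouring cortex or subiculum in the dissected tissue as a candidate source, where 6 of the 7 cortical markers on the array lay over the filter in this tissue and 1, Nr4a2, is in another list. Thalamus as the source of Slc17a6 cannot be told apart from cortex, since the 7 other thalamic markers on the array had a median difference of 0.000173 log2 between high and low but 5 of them lay below the filter. Chance was not excluded for the cortical list (exact permutation, adjusted p = 0.112 between high and low), and an effect of diet stays open and untested.

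Vessel markers were lower on the high diet than on control in 11 of 11 endothelial genes, with a median of -0.089 log2, and in 4 of 4 mural genes, with a median of -0.057. The difference of these medians was -0.032, but with all 15 markers lower neither median can lie above 0, so a smaller share of vessels in the high-diet tissue cannot be told apart from lower expression in the vessels. The vessel score and the cortical score varied in opposite directions over 26 rats after removal of the diet means (Pearson r = -0.474, permutation p = 0.0177, adjusted p = 0.0266 over 3 relations; Spearman rho = -0.446, permutation p = 0.0306; r = -0.492 without the 2 rats farthest from the median), but this takes cage mates as independent, and it did not hold over the means of 14 cages (r = -0.395, permutation p = 0.262, adjusted p = 0.393; rho = -0.398, permutation p = 0.233; r = -0.174 without the 2 farthest cages). The cortical and CA1 scores gave r = -0.432 (permutation p = 0.0556, adjusted p = 0.0556; rho = -0.378, permutation p = 0.0747; r = -0.418 without those 2 rats), and over cages r = -0.215 (permutation p = 0.669, adjusted p = 0.669; rho = 0.0066, permutation p = 0.991; r = 0.316 without the 2 farthest cages). Chance was not excluded by the exact permutation (adjusted p = 0.0582 between high and control), and an effect of diet on the vessels stays open and untested.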

How the results depend on the processing

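The fits without the 3 arrays of lowest quality weight (control rat 17, low rat 7 and high rat 19), the exact permutation of list scores and the relations over cages were chosen after seeing the data. With a count of 0 genes for each contrast, the settings that kept 0 calls throughout were no filter, a stricter intensity filter, every probe set tested, centring, cage as a block, array weights, an intensity trend, only the diets compared, no moderation and a threshold of 0.05. The causes of the changes below were not tested, except that a filter changes the number of genes tested. With no filter the genes at an unadjusted p under 0.05 numbered 625 (3 diets), 649 (high and control), 453 (low and control) and 681 (tail mark), and 3 lists were called between high and control. With the stricter filter these were 203, 373 (high and low), 201, 71 and 282, with 3, 0 and 1 lists called between high and low, high and control, and low and control, where 5, 4 and 1 of the called lists could be tested. Quantile normalization gave 1 gene between high and low and 3 lists between high and control, and the tail mark as a covariate gave 1 gene between high and low. With cage as a block 255 genes (3 diets) and 128 (low and control) were at an unadjusted p under 0.05. Removal of values over 2 SD gave 16, 30 and 15 called genes for the 3 diets, high and low, and high and control, with 717 (3 diets), 665 (high and control) and 358 (low and control) at an unadjusted p under 0.05, and 1 list between low and control. With removal and no moderation 19 genes were called and 738 were at an unadjusted p under 0.05. An estimated correlation left 0, 1 and 0 lists, and the exact permutation 0, 0 and 0. Without the 3 arrays 1, 5 and 1 genes were called (Fabp3 for the 3 diets and for high and control, and Atp2b4, Camk2d, Gabra3, Hpcal1 and Tmem53, with adjusted p = 0.0938, for high and low, named after their values were seen, Gabra3 apart), and 1 list between low and control. At 0.31, 2 genes were called between high and low, and 392 genes at an unadjusted p under 0.05 were assigned a pattern. Leaving out 1 rat gave 0 to 3 genes (3 diets), 0 to 3 (high and low), 0 to 1 (high and control), 0 to 0 (low and control) and 0 to 1 (tail mark), and at an unadjusted p under 0.05 it gave 324 to 496, 508 to 774, 312 to 506, 161 to 249 and 361 to 532. Lists then numbered 6 to 11, 4 to 6 and 1 to 6. Zbtb20 between low and control turned to -0.0095 with removal (adjusted p = 0.999), and the microglial list to -0.0061 without low rat 5, against up to +0.058 without another rat. Of the other values of named genes 3775 kept direction and side and 30 passed, and of the list values 522 kept both and 63 lost the call; the vessel list between high and control kept its call in the 36 settings where camera was run on it, which exclude the stricter filter (4 genes left, too few to test) and the exact permutation, by which it was not called (adjusted p = 0.0582). No setting combined cage as a block with an estimated correlation. Over cages the relation of the cortical and vessel scores was no longer past 0.05 (r = -0.395, adjusted p = 0.393). Genes near background, such as Vdr, were limited by their low signal.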

Other observations

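The tests given here were planned before their results were seen, except the swaps of tail marks within cages and the fit without 3 arrays, and the genes Cd74, Cd3e, Npas4 and Ttr were chosen after their values were seen.

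Markers of some cell types not yet described varied widely between rats. Ttr, a transthyretin gene of the choroid plexus, ranged from 6.69 to 12.9 log2 over the arrays, with means of 9.15 ± 0.98 on low, 9.40 ± 1.79 on control and 8.88 ± 1.64 on high, and it had the lowest difference between high and control, -0.52. The highest Ttr value came from control rat 16, which also had the highest value of Kl, 7.54. The MHC class II chain Cd74 had the highest difference between low and control, +0.50 (SE 0.30), and between high and control, +0.44 (SE 0.29), with limma adjusted p values of 1.00 in both. The T-cell gene Cd3e had the lowest difference between high and low, -0.33 (SE 0.14), and the activity-induced gene Npas4 the lowest between low and control, -0.42 (SE 0.32). Over the filter were 3 choroid plexus, 4 meningeal, 3 thalamic and 0 red blood cell markers, too few for a list test.

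The other 13 lists were not called between high and low. Glucocorticoid-induced genes had a median of -0.065 (12 of 16 lower, adjusted p = 0.150, or 0.142 between low and control with a median of +0.035), and 3 passed when adjusted over the list alone at 0.17 and 0 at 0.05. This list was called, lower on high than on low, without the 3 arrays of lowest weight (0.00614) and without low rat 3 (0.0183), low rat 6 (0.0199) or low rat 7 (0.0145). Between low and control it was called, higher on low, without low rat 3 (0.0114), low rat 6 (0.0135), low rat 7 (0.00922), control rat 13 (0.00497) or control rat 15 (0.0381). These calls used the preset correlation. Over all rats an estimated correlation gave this list an adjusted camera p of 0.786 in both contrasts. Further lists called between high and low with 1 rat left out were circadian clock without low rat 4 (0.0464), and microglia (0.0236) and oligodendrocyte and myelin (0.0362) without low rat 6. Between low and control these were, higher on low, dentate gyrus without low rat 1 (0.0376), antigen presentation (0.0362) and oligodendrocyte and myelin (0.0116) without low rat 6, and calcium without low rat 7 (0.0159), and, lower on low, circadian clock without low rat 4 (0.0345) and oxidative phosphorylation without low rat 6 (0.0433) or control rat 15 (0.0368). Microglia and complement had a median of -0.025 (adjusted p = 0.309), dentate gyrus -0.024 (0.443), astrocyte -0.012 (0.273), postsynaptic density and glutamate receptors -0.010 (0.273), neurotrophic factors -0.0092 (0.317), heat shock and unfolded protein response -0.0059 (0.624), immediate early genes -0.0030 (0.987) and oligodendrocyte and myelin -0.0029 (0.802, with 1 gene passing when adjusted over the list alone at 0.17 and 0 at 0.05). The medians of circadian clock, CA3, ribosomal protein and antigen presentation genes were +0.024 (0.303), +0.016 (0.836), +0.0065 (0.734) and +0.0061 (0.904).

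Removal of values over 2 SD from their diet mean, as the series design describes, raised the genes at an unadjusted p under 0.05 in one-way ANOVA from 376 to 738, and called 19. Over the 99 other groupings of the same rats the mean count rose from 443 to 762, a ratio of 1.72. Taking out values far from their group mean lowers the spread within any grouping, and the count rose without the diet grouping too. In data simulated without any difference the count rose from 409 to 745, with 3 genes called. With the removal the other groupings of the measured rats called a mean of 55.8 genes (median 5, highest 1065). At least 19 were called in 34 of 100 groupings, the real one included. The count with the removal did not set the diets apart, since 42 of 100 groupings, the real one included, gave at least 738 genes, the highest other giving 1766. The size of the rise was not ranked over the groupings, so a share of diet in it is not excluded.

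Other splits of the rats into groups of the same sizes were counted, the real split included. For the 3 diets chance was not excluded, with 52 of 100 splits at or above the real 392 genes at an unadjusted p under 0.05 and a highest other of 1313. Between high and low it was not excluded for the 613 genes (12 of 100 splits, highest other 1818). For the 8 called lists 3 of 100 splits called as many (highest other 10), but these splits part cage mates. That count was not adjusted for the number of split counts made here. The exact permutation of list scores, which parts cage mates too, called 0 lists between high and low. Chance was therefore not excluded for the lists. With whole cages kept together chance was not excluded for the genes (36 of 70 splits, highest other 2083) or the lists (5 of 70, highest other 11). Between high and control it was not excluded for the 393 genes (36 of 100, highest other 2072) or the 6 lists (13 of 100, highest other 10), nor with whole cages (42 of 70, highest other 1787, and 12 of 70, highest other 11). Between low and control it was not excluded for the 193 genes (96 of 100, highest other 1086) or the 2 lists (91 of 100, highest other 9), nor with whole cages (67 of 70, highest other 2194, and 61 of 70, highest other 9). For the tail mark it was not excluded for the 451 genes when marks were redrawn within each diet regardless of cage (38 of 100, highest other 1445). Nor was it when marks were swapped only between cage mates, in the same fit (13 of 100, highest other 625) or for the 606 genes with cage as a random block (6 of 40, highest other 835). Splits of the diets with several times the real count point to a structure of the samples, and what that structure is was not tested. The first 2 principal components held 14.9% and 13.8% of the variance.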
